A study of Homo sapiens and Mus musculus with 56 samples.

How the data were processed

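Total RNA from 5 leukaemia cell models (RS4;11, SEM, REH, MOLM-13 and mouse MLL-AF9 cells) was profiled on 56 Affymetrix arrays, 44 human and 12 mouse, in 20 groups of 2 or 3 arrays. Per the labels, cells received DMSO, EPZ004777, MI-2-2 (also spelled MI2-2 there) or a combination of both compounds, whose doses were read as those of the single compounds, and RNA was amplified with the Nugen Ovation method and hybridized as biotin-labelled cDNA. RS4;11 has 2 DMSO arrays and SEM has 2 arrays in each group other than EPZ004777, and the number of arrays limits the precision of each change. The deposited values are log2 signals per probe set, made by the authors with RMA in the affy package under R 3.0.2, according to the submitters' processing notes. The values were used as given, and the array medians lay between 5.54 and 6.25.

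Probe sets were joined to gene symbols through the platform annotation, with human symbols updated by Entrez identifier (41043 of 41097 probe sets with 1 symbol) and mouse symbols kept as annotated. Of 54675 human probe sets, 41097 had exactly 1 symbol, 1801 had several and 11777 had none, and of 45101 mouse probe sets the numbers were 34958, 932 and 9211. Those with several symbols or none and the control probe sets (62 human, 64 mouse) were left out, which removes HOXA9 from the human arrays. Per gene the probe set with the highest mean over the arrays of a fit was taken, and the gene was kept if that probe set lay above percentile 40 of the array on at least 2 arrays. A probe set whose identifier ends in _s_at or _x_at may bind transcripts other than those of the gene it is annotated to, and genes read on such a probe set carry the mark † in the report.

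Each cell model was fitted on its own in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, default settings), with 1 coefficient per treatment group, so that the 4 groups share an estimate of the spread. The 7 contrasts were each treatment against DMSO, the combination against either compound, EPZ004777 against MI-2-2, and the interaction (combination minus EPZ004777 minus MI-2-2 plus DMSO). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no threshold on the fold. The difference between lines was tested in a fit of the 32 arrays of RS4;11, SEM and REH (12 groups) as the mean effect in RS4;11 and SEM minus the effect in REH. MOLM-13 and the mouse cells had another MI-2-2 dose and another duration and were not tested against REH.

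The 13 gene lists, their members, the filter, the contrasts and the rule for named genes were chosen before the data were examined. Each list with at least 5 measured members was tested with camera at an inter-gene correlation of 0.01, two-sided, with p-values adjusted over the lists and 3 treatments of a cell model, and the correlation estimated from the residuals was an alternative. KMT2A fusion targets and stem cell genes share 2 members. Named genes were, per model and treatment, the 5 largest rises and 5 largest falls among called genes whose treated arrays all lay on the same side of all DMSO arrays, a separation that chance gives to 10% of genes with 3 against 3 arrays, up to 3 called members of each list, and HOXA9, MEIS1, DOT1L and MEN1. For other contrasts the 3 largest rises and falls were taken, passing over symbols without a given gene name. The report prints a part of these, mostly those whose call held when any array was left out.

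Similarity of the compounds was the correlation and covariance of their log2 changes beside 200 simulations of unchanged groups that share the DMSO arrays, and overlap between models was set beside n1 x n2 / N. A self-test on simulated data drawn from the probe set means and residual spread of the arrays recovered 59.7% of changes of 0.5 log2 for EPZ004777 minus DMSO in REH, 74.6% in RS4;11, 67.2% in SEM, 83.6% in MOLM-13 and 16.4% in the mouse cells, and of changes of 2 log2 98.5% in RS4;11 and 100% in each other model. The alternatives planned were no filter, quantile normalization again, the mean of probe sets, replicate number as a block, a fit shared by the 44 human arrays, leaving out each array, the estimated correlation, and an adjusted p under 0.01 for the overlaps. Added after seeing the data were fits without REH DMSO replicates 1 and 3, without mouse combination replicates 2 and 3, with the GAPDH or actin 3' minus 5' value as a covariate, and with array weights. Array weights were also run for the mouse cells, where the estimate did not converge (weights 0.026 to 16.6), and were not used there. A change of sign that was uncalled on both sides was counted as the same result.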

Results

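Gene expression was measured on Affymetrix arrays in 5 leukaemia cell models. The cells were treated with EPZ004777, an inhibitor of the histone methyltransferase DOT1L, with MI-2-2, an inhibitor of menin, with a combination of both compounds, or with DMSO. RS4;11 and SEM are human B-precursor lines with a KMT2A-AFF1 fusion, and REH is a human B-precursor line without a KMT2A fusion. MOLM-13 is a human acute myeloid leukaemia line with a KMT2A-MLLT3 fusion, and the mouse cells carry MLL-AF9. RS4;11, SEM and REH received 3 µM EPZ004777 or 10 µM MI-2-2 for 6 days, and MOLM-13 and the mouse cells 3 µM of either compound for 4 days. The design text describes the replicates as biological, and the 56 arrays give 2 or 3 per group, which limits the precision. Values after a gene name are log2 changes ± standard error, and † marks a probe set that may also bind transcripts other than those of the gene named. Genes were called at an adjusted p under 0.05 in limma, and 13 gene lists were tested with camera. Numbers of list members called over all genes are followed by the numbers when p-values are adjusted over the list alone. A range of adjusted p after the loss of a list call spans its alternatives except the estimated correlation, the losses included.

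**Figure D1:**
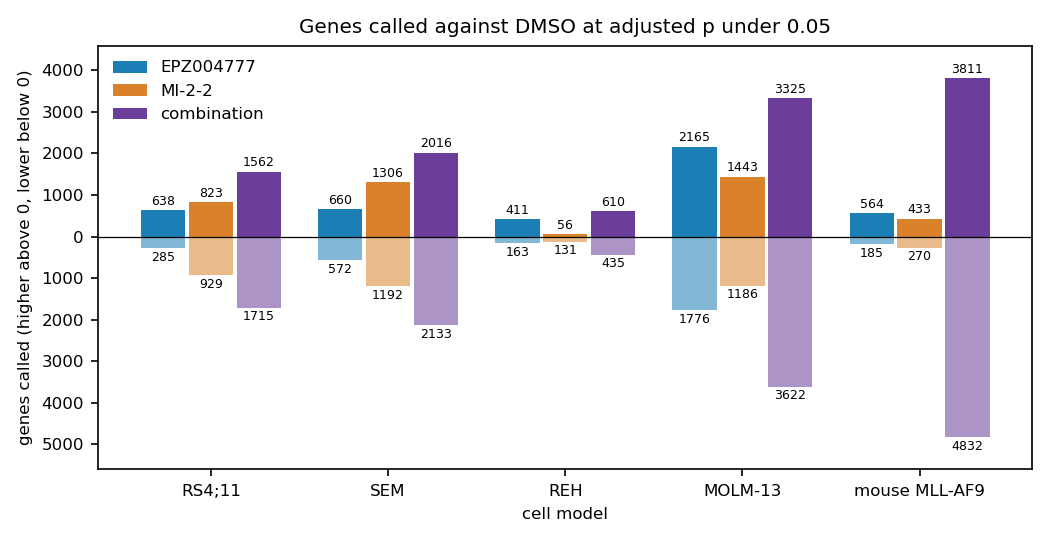
Number of genes called higher (above 0) and lower (below 0) than DMSO at an adjusted p under 0.05, for each cell model and treatment. The combination has the tallest bars in each of the 5 models.

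MEIS1, which encodes a homeobox cofactor of HOXA9 and is a known target of KMT2A fusion proteins, fell in the cells with the MLLT3 type of fusion. In MOLM-13 (n = 3 arrays per group) it changed by -1.19±0.06 with EPZ004777, -1.5±0.06 with MI-2-2 and -4.29±0.06 with the combination (adjusted p = 3.4e-07, 1.1e-07 and 2.6e-11). In the fit of all 44 human arrays the EPZ004777 call was lost (adjusted p = 0.0714, the highest of its alternatives). In the mouse cells Meis1 changed by -0.58±0.09 with MI-2-2 (adjusted p = 0.00378) and by -3.07±0.09 with the combination (adjusted p = 1.3e-09). With EPZ004777 the mouse value was -0.43±0.09, adjusted p = 0.0207. That call was lost without EPZ004777 replicate 1, 2 or 3 or DMSO replicate 1 or 3 (adjusted p 0.0869, 0.0865, 0.0511, 0.0802 and 0.0833). The mean of all probe sets ended both single-compound calls (0.556 and 0.202). MEIS1 was instead higher with the combination by 0.30±0.05, adjusted p = 0.00201, in RS4;11 and by 0.34±0.06, adjusted p = 0.00536, in SEM. The 44-array fit did not keep these calls (adjusted p = 0.754 and 0.728). With MI-2-2 alone MEIS1 was higher by 0.21±0.05, adjusted p = 0.0263, in RS4;11, lost without any 1 of its MI-2-2 or DMSO arrays (0.0511 to 0.134). In SEM it was higher by 0.31±0.06, adjusted p = 0.0122, lost without MI-2-2 replicate 1 (0.0667), DMSO replicate 2 (0.0738) or DMSO replicate 3 (0.0712). MEIS1 did not pass the filter on dim probe sets in REH.

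HOXA9 has no human probe set annotated with its symbol alone and was not analysed in the human lines. In the mouse cells Hoxa9 was not called for any treatment (-0.16±0.11, -0.08±0.11 and 0.19±0.11). DOT1L and MEN1† were not called against DMSO in any human line. In the mouse combination Dot1l was lower (-1.0±0.24, adjusted p = 0.00403) and Men1 was not called (0.10±0.14).

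In RS4;11 (n = 3 arrays per treated group and 2 for DMSO), EPZ004777 raised HOPX† (2.85±0.08, adjusted p = 4.70e-08), which encodes a homeodomain-only protein. DACT1 (2.82±0.10), an antagonist of Wnt signalling, SPP1† (2.78±0.13), the secreted phosphoprotein osteopontin, and CA2 (2.40±0.16), a carbonic anhydrase, rose as well, and ANGPT1 (-1.47±0.08, adjusted p = 3.05e-06), a ligand of the TEK receptor, fell. B cell differentiation genes rose as a list (list adjusted p = 0.00188, and adjusted p = 0.0561 with an estimated correlation). Over all genes 5 of 25 members rose and 0 fell (6 and 3 over the list alone), among them VPREB3 (1.21±0.09, adjusted p = 1.76e-05), a pre-B cell receptor protein, and BLNK† (0.83±0.08), an adaptor of that receptor. In the myeloid list 5 of 16 members rose and 0 fell (7 and 1 over the list alone), including the transcription factor gene CEBPA (0.66±0.11, adjusted p = 0.00442). Its test gave list adjusted p = 0.0136, and adjusted p = 0.143 with an estimated correlation. MHC class II presentation passed with 1 up and 0 down of 11, 2 and 0 over the list alone (list adjusted p = 0.00316, and adjusted p = 0.0561 with an estimated correlation). KMT2A fusion targets showed no shift as a list (3 up and 2 down of 18, 5 and 4 over the list alone, list adjusted p = 0.714), and the testis cyclin gene CCNA1 (1.70±0.17, adjusted p = 0.000173) was the member with the largest rise. The integrated stress and unfolded protein response list was lower by its test, with 0 up and 1 down of 22, 0 and 1 over the list alone (list adjusted p = 0.0127, and adjusted p = 0.551 with an estimated correlation). This call was lost without EPZ004777 replicate 3 or DMSO replicate 3 (adjusted p 0.00199 to 0.103). In all, 923 of 13921 genes were called, 638 up and 285 down, and 353 to 770 with 1 array left out.

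MI-2-2 in RS4;11 raised JCHAIN (4.07±0.14, adjusted p = 1.51e-07), the joining chain of polymeric immunoglobulins, SLC6A13† (3.69±0.16), a GABA transporter, and ABCG1† (3.48±0.16, adjusted p = 4.37e-07), a cholesterol exporter. SERPINE2 (-1.85±0.07, adjusted p = 1.67e-07), a protease inhibitor, and SOCS2 (-1.65±0.10), a feedback inhibitor of cytokine signalling, fell. The stress list fell as a group, since 0 of 22 members rose and 16 fell (0 and 19 over the list alone). Among the largest falls were STC2 (-1.43±0.13, adjusted p = 6.39e-05) and CHAC1 (-1.38±0.20), which degrades glutathione. The list median was -0.46 (list adjusted p = 6.97e-12, and adjusted p = 0.0561 with an estimated correlation). Genes of MHC class II presentation rose as a list, 3 up and 0 down of 11, 3 and 0 over the list alone, led by HLA-DMB (0.65±0.08, adjusted p = 0.0003), a chaperone of peptide loading. The test gave list adjusted p = 0.00508, and adjusted p = 0.0573 with an estimated correlation. Myeloid genes rose too, 6 up and 0 down of 16, 7 and 2 over the list alone, among them CD86 (1.74±0.15), a T cell costimulatory ligand. That test gave list adjusted p = 0.0305, and adjusted p = 0.19 with an estimated correlation, and the call was lost without MI-2-2 replicate 3 (adjusted p 0.000985 to 0.0731). MS4A1 (1.34±0.17, adjusted p = 0.000465), the gene of the B cell antigen CD20, was higher and DNTT (-0.76±0.07), the lymphoid terminal transferase, lower, while the B cell list did not pass (list adjusted p = 0.535). Calls numbered 1752 (823 up, 929 down), and 892 and 760 without DMSO replicate 2 and DMSO replicate 3.

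With the combination in RS4;11, UTS2† (5.71±0.19), the gene of the peptide urotensin, JCHAIN (5.24±0.14, adjusted p = 2.34e-09), MS4A1 (4.76±0.17, adjusted p = 1.36e-08) and ABCG1† (4.18±0.16) rose. PRSS12 (-4.22±0.07, adjusted p = 6.15e-11), a serine protease, and SOCS2 (-2.81±0.10) fell. In the stress list 0 of 22 members rose and 18 fell (0 and 19 over the list alone), with CHAC1 (-2.07±0.20) and TRIB3 (-1.94±0.15, adjusted p = 6.19e-06), a pseudokinase induced by ATF4, among the falls. The median was -0.80 (list adjusted p = 5.54e-12, and adjusted p = 0.0561 with an estimated correlation). MHC class II presentation rose, 7 up and 0 down of 11, 8 and 0 over the list alone, with HLA-DMB (1.27±0.08, adjusted p = 7.67e-07) and HLA-DMA† (0.77±0.07) (list adjusted p = 2.74e-06, and 0.0375 with an estimated correlation). B cell genes moved both ways, 13 up and 5 down of 25, 13 and 5 over the list alone, with MS4A1, MME† (2.50±0.11), the antigen CD10, and VPREB3 (1.97±0.09) higher. The B cell test was upward (list adjusted p = 0.00188, and adjusted p = 0.0561 with an estimated correlation). Myeloid genes rose, 6 up and 0 down of 16, 6 and 0 over the list alone, with CD86 (3.84±0.15, adjusted p = 3.59e-08) and CEBPA (1.47±0.11) (list adjusted p = 0.00707, and adjusted p = 0.114 with an estimated correlation). KMT2A fusion targets did not shift as a list (5 up and 7 down of 18, 5 and 8 over the list alone, median -0.19, list adjusted p = 0.38), as CCNA1 (3.02±0.17) rose and RUNX2 (-1.46±0.08, adjusted p = 3.12e-07) fell. Calls numbered 3277 (1562 up, 1715 down), and 1810 to 3320 with 1 array left out.

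The remaining lists did not pass in RS4;11 for any treatment. With the combination, cell cycle had 1 up and 2 down of 26 (list adjusted p = 0.66), MYC and ribosome biogenesis 0 up and 2 down of 15 (list adjusted p = 0.0749) and interferon response 4 up and 1 down of 18 (list adjusted p = 0.199). Sterol synthesis had 0 up and 2 down of 15 (list adjusted p = 0.199), p53 targets and apoptosis 1 up and 1 down of 16 (list adjusted p = 0.894) and stem and progenitor genes 2 up and 4 down of 13 (list adjusted p = 0.894). Markers of other cell types had 2 up and 0 down of 5 (list adjusted p = 0.388) and the inhibitor target complexes 0 up and 4 down of 14 (list adjusted p = 0.178).

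In direct comparison with EPZ004777 alone, the RS4;11 combination had higher MS4A1 (4.06±0.15, adjusted p = 3.83e-08) and lower PRSS12 (-3.74±0.06). Its stress list was lower, 0 up and 17 down of 22 (list adjusted p = 3.07e-13, and adjusted p = 0.0607 with an estimated correlation), and MHC class II higher (list adjusted p = 0.000342, and 0.0498 with an estimated correlation). Against MI-2-2 alone MS4A1 (3.41±0.15) was higher and PRSS12 (-2.68±0.06) lower. B cell genes were higher there, 10 up and 0 down of 25 (list adjusted p = 2.06e-06, and 0.0196 with an estimated correlation). Between the single compounds, SERPINE2 (2.54±0.06) was higher with EPZ004777 and SLC6A13† (-3.61±0.14) with MI-2-2. The stress list was higher with EPZ004777, 14 up and 0 down of 22 (list adjusted p = 5.60e-09, and adjusted p = 0.116 with an estimated correlation). These contrasts called 2719 genes, 1501 (981 without MI-2-2 replicate 1) and 2255 (1482 without EPZ004777 replicate 2). The combination departed from the sum of the single effects, on the log2 scale, for 269 genes, of which 86 rose and 30 fell beyond that sum and 153 changed less. MS4A1 (2.71±0.22, adjusted p = 0.000169) lay above the sum and HOPX† (-1.90±0.11) below it. The number was 107 to 264 with 1 array left out.

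In SEM (n = 3 arrays for EPZ004777 and 2 for each other group), EPZ004777 raised MPEG1 (3.45±0.21, adjusted p = 0.00013), which encodes the macrophage pore protein perforin-2, and ZNF521 (2.49±0.16), a zinc finger protein of progenitor cells. TPH2 (-1.59±0.13), a serotonin-synthesis enzyme, fell. B cell genes rose, 8 up and 0 down of 25, 8 and 1 over the list alone, among them BLNK† (2.19±0.15, adjusted p = 0.000226) and SPIB (1.14±0.14), an ETS factor of B cells. The list test gave list adjusted p = 0.000696, and adjusted p = 0.416 with an estimated correlation. Myeloid genes rose as well, 5 up and 1 down of 22, 8 and 1 over the list alone, with CD86 (1.14±0.09, adjusted p = 0.000504) (list adjusted p = 0.00209, and adjusted p = 0.307 with an estimated correlation). KMT2A fusion targets did not pass as a list (2 up and 6 down of 18, 4 and 8 over the list alone, list adjusted p = 0.235), though CCNA1 (1.91±0.09, adjusted p = 0.000113) rose and HMGA2† (-0.92±0.06) fell. The stress list was lower by its test with 0 up and 0 down of 22, 0 and 5 over the list alone (list adjusted p = 0.0126, and adjusted p = 0.554 with an estimated correlation). It was lost without EPZ004777 replicate 1 and in 3 other settings (adjusted p 0.00429 to 0.126). Calls numbered 1232 (660 up, 572 down), and 296 to 1755 with 1 array left out.

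MI-2-2 in SEM raised MPEG1 (4.99±0.23), MS4A1 (4.44±0.18, adjusted p = 1.16e-05), CCNA1 (4.30±0.10, adjusted p = 1.68e-06) and LYZ† (4.00±0.12, adjusted p = 3.18e-06), the gene of lysozyme. TPH2 (-3.42±0.14) and ATF5† (-2.77±0.15), a stress-response transcription factor, fell. In the stress list 1 of 22 members rose and 13 fell (2 and 18 over the list alone), with TRIB3 (-1.22±0.11, adjusted p = 0.000274) and STC2 (-1.07±0.13) lower. Its median was -0.38 (list adjusted p = 2.27e-07, and adjusted p = 0.385 with an estimated correlation). Myeloid genes rose, 8 up and 1 down of 22, 9 and 1 over the list alone, with LYZ and CD86 (3.05±0.10) (list adjusted p = 8.71e-05, and adjusted p = 0.307 with an estimated correlation). B cell genes moved up as a list, 11 up and 5 down of 25, 13 and 6 over the list alone, with BLNK† (2.87±0.16) and SPIB (2.23±0.15) (list adjusted p = 0.00351, and adjusted p = 0.416 with an estimated correlation). So did MHC class II genes, 7 up and 1 down of 11, 9 and 2 over the list alone, with HLA-DMB (1.32±0.14, adjusted p = 0.000684) (list adjusted p = 0.00209, and adjusted p = 0.416 with an estimated correlation). Interferon response genes rose, 8 up and 0 down of 17, 9 and 0 over the list alone, with IFITM1† (1.04±0.11) (list adjusted p = 0.000213, and adjusted p = 0.307 with an estimated correlation). In the cell cycle list 7 of 26 members rose and 0 fell (16 and 0 over the list alone), with CCNE1 (0.65±0.08) (list adjusted p = 6.88e-06, and adjusted p = 0.307 with an estimated correlation). Calls numbered 2498 (1306 up, 1192 down), and 1143 to 1528 with 1 array left out.

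The actin 3' minus 5' value, a sign of RNA quality, was 1.83 to 1.93 on the MI-2-2 and combination arrays of SEM and 2.32 to 2.48 on its DMSO and EPZ004777 arrays. The GAPDH value was 0.282 to 0.386 on all 9. With the actin value as a covariate, added after seeing the data, limma called 0 genes for MI-2-2 (924 at an unadjusted p under 0.05) and 14 for the combination. The median standard error for MI-2-2 went from 0.105 to 0.546, and 101 of 145 calls of named genes in SEM ended. The MI-2-2 stress and cell cycle calls were lost with it (adjusted p 6.62e-12 to 0.704 and 4.35e-07 to 0.0628).

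The combination in SEM raised LYZ† (6.33±0.12, adjusted p = 1.26e-07), MPEG1 (6.29±0.23) and CCNA1 (5.61±0.10, adjusted p = 1.26e-07). TPH2 (-3.62±0.14) and CHAC1 (-3.49±0.26, adjusted p = 4.78e-05) fell. The stress list fell, 1 up and 20 down of 22, 1 and 20 over the list alone, with CHAC1 and SLC7A11 (-2.85±0.17, adjusted p = 1.65e-05), the cystine transporter. Its median was -1.16 (list adjusted p = 1.93e-11, and adjusted p = 0.307 with an estimated correlation). Among the KMT2A fusion targets 4 of 18 members rose and 12 fell (4 and 12 over the list alone), with the progenitor antigen gene PROM1† (-2.23±0.07, adjusted p = 8.93e-07) lower and CCNA1 and EYA1† (2.83±0.20) higher. The list had a median of -0.45 and a mean of -0.08 (list adjusted p = 0.00338, and adjusted p = 0.307 with an estimated correlation). ERG† (-2.77±0.07, adjusted p = 4.94e-07), a transcription factor gene of haematopoietic stem cells, fell as well, though the stem cell list did not pass (3 up and 2 down of 12, list adjusted p = 0.5). Myeloid genes rose, 14 up and 2 down of 22, 16 and 2 over the list alone, with LYZ and CD86 (4.76±0.10) (list adjusted p = 8.36e-07, and adjusted p = 0.307 with an estimated correlation). MHC class II genes rose, 9 up and 1 down of 11, 9 and 1 over the list alone, with HLA-DMB (2.01±0.14) (list adjusted p = 3.52e-05, and adjusted p = 0.307 with an estimated correlation). Cell cycle genes rose, 13 up and 0 down of 26, 15 and 0 over the list alone, with CCNE1 (1.16±0.08, adjusted p = 4.25e-05) (list adjusted p = 9.46e-06, and adjusted p = 0.307 with an estimated correlation). The B cell, interferon, sterol, MYC, p53 and inhibitor target lists did not pass (adjusted p = 0.128, 0.173, 0.0963, 0.326, 0.5 and 0.205). Markers of other cell types were not tested in SEM and REH because fewer than 5 were measured. Calls numbered 4149 (2016 up, 2133 down), and 2500 to 2804 with 1 array left out.

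Compared with EPZ004777 alone, the SEM combination had higher LYZ† (5.11±0.11) and lower EDIL3 (-3.73±0.56), an integrin ligand. Stress genes were lower, 1 up and 18 down of 22 (list adjusted p = 1.17e-12, and adjusted p = 0.221 with an estimated correlation). Compared with MI-2-2 alone it had higher CCL2† (3.29±0.16), a monocyte chemokine, and lower CHAC1 (-3.11±0.26, adjusted p = 0.000532). Again stress genes were lower, 0 up and 15 down of 22 (list adjusted p = 7.33e-13, and adjusted p = 0.221 with an estimated correlation), and myeloid genes higher, 8 up and 1 down of 22 (list adjusted p = 8.68e-08, and adjusted p = 0.221 with an estimated correlation). Between the single compounds, EDIL3 (3.79±0.56) was higher with EPZ004777 and MS4A1 (-3.72±0.16) and ABCA1† (-2.88±0.07, adjusted p = 3.15e-06), a cholesterol exporter, with MI-2-2. The interferon list was higher with MI-2-2 (0 up and 13 down of 17 for EPZ004777 minus MI-2-2, list adjusted p = 1.94e-06, and adjusted p = 0.221 with an estimated correlation). These contrasts called 3754 genes (2340 and 2041 without combination replicate 1 and combination replicate 3), 675 (249 to 354 without any 1 of its combination and MI-2-2 arrays) and 3219 (1350 without MI-2-2 replicate 3). For 136 genes the combination departed from the sum of the single effects, with 39 up and 25 down beyond the sum and 72 short of it. CCL2† (3.32±0.22) lay above the sum, and the stress list below it (0 up and 3 down of 22, list adjusted p = 4.38e-09, and adjusted p = 0.186 with an estimated correlation). The 136 became 49 to 84 without any 1 of the combination, MI-2-2 and DMSO arrays or EPZ004777 replicate 3.

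In REH, which lacks a KMT2A fusion (n = 3 arrays per group), EPZ004777 raised MRC1 (2.58±0.13, adjusted p = 3.24e-07), the macrophage mannose receptor, GIMAP8 (2.25±0.09), a lymphocyte GTPase, and SDC2 (2.18±0.11), a syndecan. SULF2 (-1.95±0.18, adjusted p = 6.50e-05), a heparan sulfatase, and PRF1 (-1.62±0.19), the perforin gene, fell. The p53 targets fell, 0 up and 7 down of 16, 0 and 7 over the list alone, among them FAS† (-1.14±0.13, adjusted p = 0.000357), a death receptor, and CDKN1A† (-0.60±0.10), an inhibitor of cyclin-dependent kinases. Their median was -0.34 (list adjusted p = 3.22e-05, and adjusted p = 0.175 with an estimated correlation). The cell cycle list was higher by its test, with 2 up and 0 down of 26, 3 and 0 over the list alone (list adjusted p = 4.77e-06, and adjusted p = 0.539 with an estimated correlation). Myeloid genes passed, 4 up and 0 down of 16, 4 and 1 over the list alone, with MRC1 and IRF8 (1.37±0.12, adjusted p = 4.27e-05), a factor of monocytes and B cells (list adjusted p = 0.00806, and adjusted p = 0.324 with an estimated correlation). That call was lost without DMSO replicate 2 (adjusted p 0.00101 to 0.0737). MHC class II (1 up and 0 down of 11, 1 and 0 over the list alone) and interferon genes (2 up and 0 down of 19, 3 and 0 over the list alone) were higher and stress genes (0 up and 3 down of 21, 0 and 4 over the list alone) lower by their tests (adjusted p = 0.0148, 0.0236 and 0.0314). These became adjusted p = 0.555, 0.555 and 0.558 with an estimated correlation. Each of these 3 calls was lost without DMSO replicate 2, and some also without DMSO replicate 3 (MHC class II, stress), DMSO replicate 1 (interferon) or EPZ004777 replicate 1 (stress). They were also lost in the 44-array fit (MHC class II, interferon), with the GAPDH covariate (MHC class II, stress), the mean of probe sets (stress) or without DMSO replicates 1 and 3 (interferon, stress). Their adjusted p ranged from 9.16e-07 to 0.388, 0.00824 to 0.143 and 0.00477 to 0.350. Calls numbered 574 (411 up, 163 down), and 308 to 1058 with 1 array left out.

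MI-2-2 in REH raised AGR2 (1.17±0.12, adjusted p = 0.0018), a protein disulfide isomerase. ARRDC4 (-1.22±0.11, adjusted p = 0.00108), an arrestin-domain protein, fell. The MYC (0 up and 0 down of 15, 1 and 0 over the list alone) and cell cycle lists (0 up and 0 down of 26, 0 and 0 over the list alone) were higher and the p53 list (0 up and 3 down of 16, 0 and 5 over the list alone) lower by their tests (adjusted p = 0.0313, 0.0314 and 0.042). These became adjusted p = 0.558, 0.648 and 0.539 with an estimated correlation. Each of these calls was lost without MI-2-2 replicate 2 or DMSO replicate 2, and also without DMSO replicate 1 (MYC, cell cycle) or DMSO replicate 3 (p53). Quantile normalization again ended MYC and cell cycle, leaving out DMSO replicates 1 and 3 MYC, and the GAPDH covariate p53. Their adjusted p ranged from 0.00474 to 0.207, 4.16e-05 to 0.306 and 0.000231 to 0.294. Calls numbered 187 (56 up, 131 down), and 19 to 1314 with 1 array left out.

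The combination in REH raised SDC2 (2.88±0.11, adjusted p = 2.81e-08), CCND2† (2.14±0.12), a D-type cyclin, and KIT† (1.89±0.12), the stem cell factor receptor. SULF2 (-2.15±0.18), PRF1 (-1.67±0.19) and ITGA10 (-1.51±0.16), an integrin, fell. Of the p53 targets 0 of 16 members rose and 8 fell (0 and 8 over the list alone), among them FAS† (-1.27±0.13, adjusted p = 0.000123). The list median was -0.39 (list adjusted p = 4.25e-05, and adjusted p = 0.175 with an estimated correlation). Interferon genes were higher, 4 up and 1 down of 19, 7 and 1 over the list alone, with IFITM1† (0.76±0.10, adjusted p = 0.000827) (list adjusted p = 0.00806, and adjusted p = 0.539 with an estimated correlation). The cell cycle list was higher by its test, 2 up and 0 down of 26, 6 and 0 over the list alone (list adjusted p = 0.00365, and adjusted p = 0.558 with an estimated correlation), a call lost without DMSO replicate 2 (adjusted p 1.38e-06 to 0.0737). MHC class II genes were higher by theirs, 1 up and 0 down of 11, 3 and 0 over the list alone (list adjusted p = 0.0259, and adjusted p = 0.558 with an estimated correlation), lost without DMSO replicate 2 or DMSO replicate 3, in the 44-array fit and with the GAPDH covariate (adjusted p 8.21e-06 to 0.340). KMT2A fusion targets (1 up and 1 down of 16), myeloid, B cell, stress (0 up and 5 down of 21), sterol, MYC, stem cell and inhibitor target lists did not pass. Their adjusted p was 0.803, 0.219, 0.449, 0.442, 0.147, 0.518, 0.0599 and 0.615. Calls numbered 1045 (610 up, 435 down), and 473 to 2028 with 1 array left out.

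The actin 3' minus 5' value was 3.11 and 3.65 on REH DMSO replicates 1 and 3 and 2.36 to 2.87 on the other REH arrays. The GAPDH value of DMSO replicate 3 was 1.08, where the others had 0.407 to 0.593. Without both of these arrays, an alternative added after seeing the data, 394, 29 and 511 genes were called for EPZ004777, MI-2-2 and the combination.

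For MI-2-2 added to EPZ004777 in REH limma called 24 genes, 136 in the fit shared by the human arrays, 110 without DMSO replicates 1 and 3, 6 with the replicate block and 1648 with array weights. The 24 include RASD2 (1.15±0.15, adjusted p = 0.0163), a small GTPase whose call was lost without any 1 of the 6 arrays (adjusted p 0.0616 to 0.104). Without combination replicates 1, 2 and 3 and EPZ004777 replicates 1, 2 and 3, each alone, limma called 1, 0, 0, 0, 0 and 1, with 683, 617, 1001, 805, 753 and 906 genes at an unadjusted p under 0.05. Compared with MI-2-2 alone, SDC2 (2.06±0.11, adjusted p = 1.63e-06) and MRC1 (1.78±0.13) were higher and CYP4F3 (-1.73±0.17), a leukotriene hydroxylase, lower, and 280 genes were called. The p53 list was lower there (0 up and 1 down of 16, list adjusted p = 2.63e-05, and adjusted p = 0.249 with an estimated correlation). EPZ004777 against MI-2-2 called 389 genes, with MRC1 (2.32±0.13) higher with EPZ004777 and CYP4F3 (-1.59±0.17) with MI-2-2. With 1 array left out the 280 became 150 to 189 and the 389 became 218 to 317. For departure from the sum of the single effects limma called 0 genes, with 739 at an unadjusted p under 0.05.

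The mean effect in RS4;11 and SEM was tested against the effect in REH, which had the same doses and days and differs in many ways besides the fusion. With MI-2-2, JCHAIN (3.77±0.16, adjusted p = 3.07e-14), MPEG1 (3.47±0.26) and MS4A1 (3.42±0.25) stood higher in the lines with KMT2A-AFF1 and ATF5† (-1.79±0.12) lower. The stress list was lower, 1 up and 12 down of 22, 1 and 15 over the list alone (list adjusted p = 5.68e-09, and adjusted p = 0.0724 with an estimated correlation). Myeloid genes were higher, 7 up and 0 down of 22, 8 and 0 over the list alone (list adjusted p = 7.49e-05, and 0.0363 with an estimated correlation). With the combination, UTS2† (5.17±0.24), MPEG1 (5.06±0.26) and MS4A1 (5.05±0.25) stood higher and CHAC1 (-3.41±0.29, adjusted p = 4.02e-09) and PRSS12 (-2.66±0.54) lower. Again stress genes were lower, 1 up and 15 down of 22, 1 and 17 over the list alone (list adjusted p = 1.69e-11, and adjusted p = 0.0565 with an estimated correlation). Myeloid genes (9 up and 2 down of 22, 10 and 3 over the list alone, list adjusted p = 1.31e-05, and 0.0334 with an estimated correlation) and p53 targets (8 up and 0 down of 16, 9 and 2 over the list alone, list adjusted p = 0.000477, and adjusted p = 0.067 with an estimated correlation) were higher. The p53 list fell in REH (median -0.39), not in RS4;11 or SEM (-0.04 and 0.04). With EPZ004777, MPEG1 (2.83±0.26, adjusted p = 1.23e-07) and SULF2 (2.14±0.20), which fell in REH, stood higher and GIMAP8 (-2.13±0.18) and MRC1 (-2.09±0.20) lower. The interferon list was lower, 0 up and 3 down of 19, 0 and 6 over the list alone (list adjusted p = 0.000706, and adjusted p = 0.099 with an estimated correlation). Differences covered 784 genes with EPZ004777 (372 up, 412 down, and 1189 or 1884 without REH DMSO replicate 2 or 3). They covered 2036 with MI-2-2 (1182 up, 854 down, and 3177 without REH DMSO replicate 2) and 3099 with the combination (1499 up, 1600 down). Without REH DMSO replicates 1 and 3 the numbers were 633, 1117 and 2092.

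**Figure D2:**
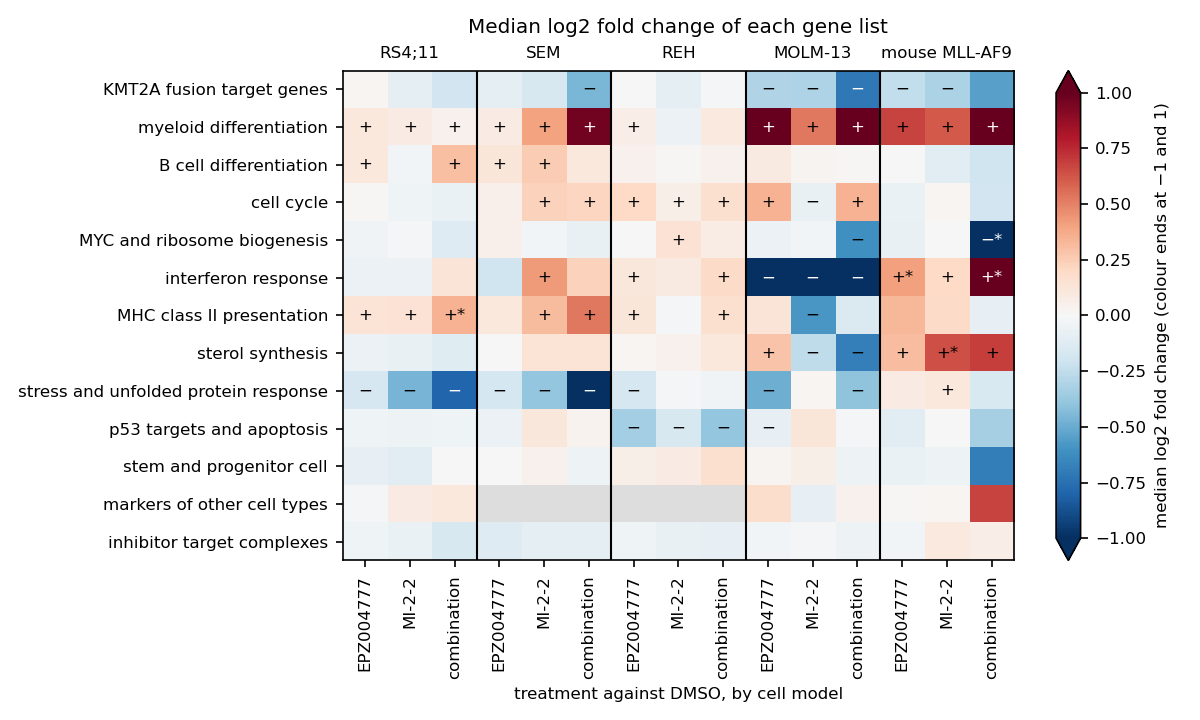
Median log2 change of the measured members of each of the 13 gene lists (vertical) for each cell model and treatment against DMSO (horizontal), red higher and blue lower. A plus or minus marks a list called by camera and an asterisk a list also called with an estimated correlation, and grey marks lists with fewer than 5 measured members.

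In MOLM-13 (n = 3 arrays per group), EPZ004777 raised PRLR (4.21±0.08, adjusted p = 2.60e-10), the prolactin receptor, and MPO (3.02±0.07, adjusted p = 1.04e-09), MNDA (2.95±0.07) and CYBB† (2.52±0.08), genes of granulocytes and monocytes. IFI44L (-4.34±0.18, adjusted p = 6.33e-08), CXCL10 (-3.66±0.33, adjusted p = 1.86e-05) and IFIT1 (-3.23±0.29), genes induced by interferon, and EGR3 (-3.68±0.39) fell. Of the interferon genes 0 of 20 members rose and 17 fell (0 and 17 over the list alone). Their median was -1.75 (list adjusted p = 6.58e-14, and adjusted p = 0.155 with an estimated correlation). Myeloid genes rose, 18 up and 1 down of 26, 20 and 1 over the list alone, with a median of 1.01 (list adjusted p = 1.27e-12, and adjusted p = 0.12 with an estimated correlation). The stress list fell, 0 up and 17 down of 22, 0 and 18 over the list alone, with STC2 (-1.83±0.13) and TRIB3 (-1.37±0.11) (list adjusted p = 7.23e-12, and adjusted p = 0.146 with an estimated correlation). Cell cycle genes rose, 23 up and 0 down of 26, 23 and 0 over the list alone, with MKI67† (0.68±0.14) (list adjusted p = 4.12e-09, and adjusted p = 0.155 with an estimated correlation). Of the KMT2A fusion targets 1 of 16 members rose and 12 fell (1 and 13 over the list alone), with MEIS1 and FLT3 (-0.86±0.07, adjusted p = 8.75e-06), a receptor tyrosine kinase, among the falls. Their median was -0.30 (list adjusted p = 4.89e-07, and adjusted p = 0.155 with an estimated correlation). The p53 list fell, 1 up and 6 down of 16, 1 and 6 over the list alone (list adjusted p = 0.0114, and adjusted p = 0.296 with an estimated correlation). Sterol synthesis was higher by its test (2 up and 0 down of 15, 0 and 0 over the list alone, list adjusted p = 0.0148, and adjusted p = 0.614 with an estimated correlation), a call lost without DMSO replicate 1 or DMSO replicate 3 (adjusted p 1.74e-05 to 0.155). Calls numbered 3941, 2165 up and 1776 down.

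MI-2-2 in MOLM-13 raised the cholesterol exporters ABCG1† (8.09±0.24, adjusted p = 1.21e-08) and ABCA1† (4.44±0.12, adjusted p = 1.06e-08), and CD14 (1.96±0.09, adjusted p = 1.97e-07), the monocyte coreceptor of lipopolysaccharide. ALDH1A3 (-4.86±0.17), a retinal dehydrogenase, IFI44L (-4.64±0.18, adjusted p = 7.32e-08) and IFIT1 (-4.53±0.29) fell. Interferon genes fell as a group, 0 up and 18 down of 20, 0 and 19 over the list alone, with a median of -2.30 (list adjusted p = 2.56e-23, and adjusted p = 0.12 with an estimated correlation). KMT2A fusion targets fell, 1 up and 10 down of 16, 1 and 11 over the list alone, with MEIS1 and the transcription factor genes MEF2C† (-0.74±0.06) and PBX3 (-0.61±0.06) (list adjusted p = 2.04e-08, and adjusted p = 0.146 with an estimated correlation). Myeloid genes rose, 14 up and 2 down of 26, 18 and 2 over the list alone, with MNDA (2.44±0.07) and CD14 (list adjusted p = 3.04e-09, and adjusted p = 0.146 with an estimated correlation). Sterol synthesis genes fell, 0 up and 7 down of 15, 0 and 7 over the list alone, with the enzyme gene HMGCS1 (-1.11±0.16, adjusted p = 0.000692) (list adjusted p = 1.48e-05, and adjusted p = 0.354 with an estimated correlation). MHC class II genes fell, 1 up and 6 down of 10, 1 and 7 over the list alone, with HLA-DRA (-1.84±0.13, adjusted p = 5.99e-06) (list adjusted p = 5.74e-05, and adjusted p = 0.12 with an estimated correlation). The cell cycle list was lower by its test (0 up and 3 down of 26, 0 and 3 over the list alone, list adjusted p = 0.0148, and adjusted p = 0.569 with an estimated correlation), a call lost without DMSO replicate 2 (adjusted p 5.17e-05 to 0.408). Stress genes did not pass (4 up and 1 down of 22, list adjusted p = 0.477). Calls numbered 2629, 1443 up and 1186 down.

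With the combination MOLM-13 had higher ABCG1† (8.82±0.24), CYP4F3 (6.27±0.14), FPR1† (4.75±0.11), a formyl peptide receptor of neutrophils, and CD14 (4.74±0.09, adjusted p = 5.72e-11). EGR3 (-4.79±0.39) and IFI44L (-4.60±0.18) were lower. Myeloid genes rose, 24 up and 1 down of 26, 24 and 1 over the list alone, with CD14 and FPR1 (list adjusted p = 6.58e-14, and adjusted p = 0.12 with an estimated correlation). KMT2A fusion targets fell, 1 up and 13 down of 16, 2 and 13 over the list alone, with MEIS1, PBX3 (-2.10±0.06, adjusted p = 5.24e-10) and FLT3 (-1.33±0.07). Their median was -0.71 (list adjusted p = 2.34e-06, and adjusted p = 0.177 with an estimated correlation). Interferon genes were lower, 1 up and 18 down of 20, 1 and 18 over the list alone (list adjusted p = 2.70e-07, and adjusted p = 0.296 with an estimated correlation). MYC and ribosome biogenesis genes fell, 0 up and 12 down of 15, 1 and 12 over the list alone, with ODC1 (-1.29±0.07) (list adjusted p = 6.83e-06, and adjusted p = 0.146 with an estimated correlation). The sterol list fell, 0 up and 11 down of 15, 0 and 12 over the list alone, with SQLE (-1.88±0.09) (list adjusted p = 0.00021, and adjusted p = 0.433 with an estimated correlation). Cell cycle genes rose, 22 up and 1 down of 26, 24 and 1 over the list alone, with UBE2C (0.70±0.06, adjusted p = 4.05e-06) (list adjusted p = 3.11e-06, and adjusted p = 0.246 with an estimated correlation). Stress genes fell, 4 up and 15 down of 22, 4 and 15 over the list alone (list adjusted p = 0.00141, and adjusted p = 0.433 with an estimated correlation). B cell (median 0.01, test downward), MHC class II, p53, stem cell, inhibitor target and other cell type lists did not pass (adjusted p = 0.588, 0.698, 0.851, 0.158, 0.949 and 0.949). Calls numbered 6947, 3325 up and 3622 down.

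Compared with EPZ004777 alone, the MOLM-13 combination had lower MEIS1 (-3.10±0.06, adjusted p = 8.21e-10) and higher ABCG1† (6.30±0.24). The sterol (0 up and 14 down of 15), MYC (0 up and 12 down of 15) and KMT2A fusion target lists (0 up and 11 down of 16) were lower (adjusted p = 1.16e-08, 8.67e-08 and 1.39e-05). These became adjusted p = 0.197, 0.0839 and 0.197 with an estimated correlation. Compared with MI-2-2 alone it had higher CYP4F3 (5.16±0.14) and lower EGR3 (-5.79±0.39). Myeloid genes were higher, 22 up and 1 down of 26 (list adjusted p = 9.82e-14, and adjusted p = 0.0839 with an estimated correlation), and KMT2A fusion targets lower, 1 up and 13 down of 16 (list adjusted p = 2.97e-05, and adjusted p = 0.197 with an estimated correlation). Between the single compounds, LIPG (3.11±0.26) was higher with EPZ004777 and ABCG1† (-5.57±0.24) and EGR3 (-4.68±0.39) with MI-2-2. Cell cycle (24 up and 0 down of 26, list adjusted p = 5.84e-15, and adjusted p = 0.0839 with an estimated correlation) and MHC class II genes (8 up and 0 down of 10, list adjusted p = 1.36e-08, and 0.0335 with an estimated correlation) were higher with EPZ004777. Stress genes were higher with MI-2-2 (0 up and 18 down of 22 for EPZ004777 minus MI-2-2, list adjusted p = 3.75e-16, and adjusted p = 0.0839 with an estimated correlation). These contrasts called 4690, 5576 and 2958 genes. For 1816 genes (1186 without EPZ004777 replicate 2) the combination departed from the sum, 283 up and 824 down beyond it and 709 short. Interferon genes fell less than the sum, with IFI44L (4.38±0.25, adjusted p = 1.09e-05) and IFIT1 (3.17±0.41) (17 up and 0 down of 20, list adjusted p = 7.65e-22, and adjusted p = 0.0647 with an estimated correlation). A high DMSO level would give this too. The MYC list fell beyond the sum (0 up and 11 down of 15, list adjusted p = 4.20e-09, and adjusted p = 0.0568 with an estimated correlation).

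**Figure D3:**
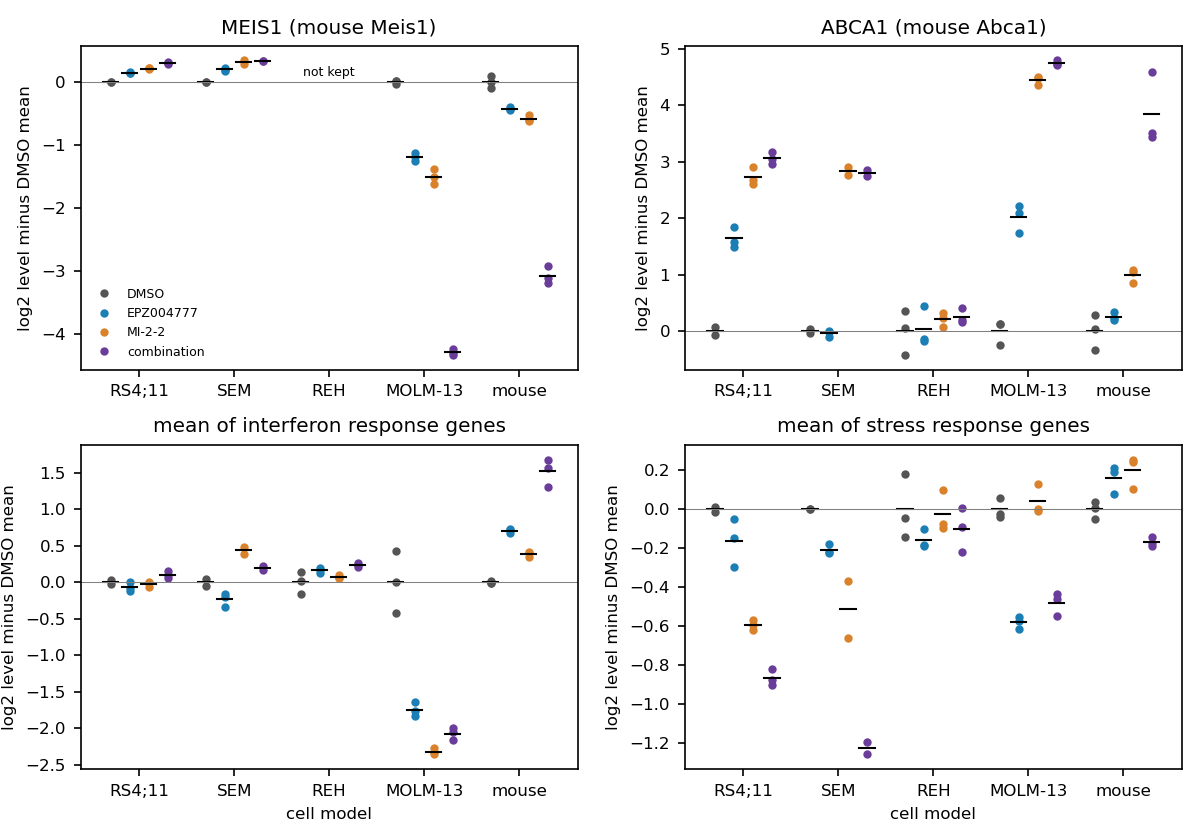
Level of MEIS1, of ABCA1, and the mean level of the interferon response and stress lists on each array, as log2 value minus the DMSO mean of the cell model, by cell model and treatment. Points are arrays and bars group means, and the MOLM-13 combination lies lowest for MEIS1 in the human lines.

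In the mouse MLL-AF9 cells (n = 3 arrays per group), EPZ004777 raised Ceacam10 (3.81±0.18, adjusted p = 2.11e-06), a cell adhesion molecule of granulocytes, and Ifitm3 (2.33±0.14, adjusted p = 4.84e-06), an interferon-induced membrane protein. Tpm2 (-2.94±0.20), a tropomyosin, and Cd34 (-2.46±0.40, adjusted p = 0.00377), an antigen of progenitor cells, fell. Myeloid genes rose, 9 up and 0 down of 23, 10 and 0 over the list alone, with Fcgr1 (2.34±0.23, adjusted p = 0.000122), a receptor of immunoglobulin G (list adjusted p = 1.14e-07, and adjusted p = 0.256 with an estimated correlation). Interferon genes rose, 3 up and 0 down of 16, 6 and 0 over the list alone, with Ifitm3 and Ifit1 (2.14±0.37) (list adjusted p = 2.11e-05, and 0.0216 with an estimated correlation). Sterol synthesis genes rose, 5 up and 0 down of 16, 8 and 0 over the list alone (list adjusted p = 1.76e-07, and adjusted p = 0.0986 with an estimated correlation). In the KMT2A fusion target list 1 of 24 members rose and 4 fell (2 and 6 over the list alone), with Pbx3† (-1.27±0.12, adjusted p = 0.000112) and Flt3 (-1.66±0.29) lower and Prom1 (2.30±0.13) higher. The test was downward (list adjusted p = 0.00011, and adjusted p = 0.0706 with an estimated correlation). Calls numbered 749 (564 up, 185 down), and 456 to 628 with 1 array left out.

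MI-2-2 in the mouse cells raised Car4 (3.85±0.35), a carbonic anhydrase, Ceacam10 (3.79±0.18) and Ltf (3.68±0.23, adjusted p = 5.99e-06), the gene of lactoferrin, and lowered Tpm2 (-4.46±0.20) and Cd34 (-3.50±0.40, adjusted p = 0.000442). Sterol synthesis genes rose, 12 up and 0 down of 16, 15 and 0 over the list alone, with Mvd† (1.30±0.13, adjusted p = 0.000171) and Fdft1† (1.20±0.12), squalene synthase. Their median was 0.64 (list adjusted p = 1.35e-21, and 0.0216 with an estimated correlation). Myeloid genes rose, 9 up and 1 down of 23, 11 and 2 over the list alone (list adjusted p = 2.22e-06, and adjusted p = 0.291 with an estimated correlation). KMT2A fusion targets fell, 1 up and 5 down of 24, 1 and 10 over the list alone, with Flt3 (-1.83±0.29, adjusted p = 0.00379) (list adjusted p = 4.98e-05, and adjusted p = 0.0706 with an estimated correlation). The interferon (1 up and 0 down of 16, 2 and 0 over the list alone, list adjusted p = 0.00934, and adjusted p = 0.0706 with an estimated correlation) and stress lists (0 up and 0 down of 22, 0 and 0 over the list alone, list adjusted p = 0.0109, and adjusted p = 0.181 with an estimated correlation) were higher by their tests. Calls numbered 703 (433 up, 270 down), and 416 to 671 with 1 array left out.

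The combination in the mouse cells raised the neutrophil genes Ceacam10 (7.89±0.18, adjusted p = 3.54e-10) and Ltf (7.57±0.23), and lowered Angpt1 (-5.14±0.23), Cd34 (-4.17±0.40) and Mef2c (-3.61±0.20, adjusted p = 9.83e-08). In the MYC and ribosome biogenesis list 0 of 20 members rose and 19 fell (0 and 19 over the list alone), with Nop16 (-3.54±0.32) and Srm (-2.85±0.13, adjusted p = 1.84e-08). Its median was -1.63 (list adjusted p = 2.22e-06, and 0.0408 with an estimated correlation). Myeloid genes rose, 18 up and 1 down of 23, 18 and 1 over the list alone, with Cybb (5.16±0.42) (list adjusted p = 3.68e-06, and adjusted p = 0.291 with an estimated correlation). Interferon genes rose, 12 up and 1 down of 16, 12 and 1 over the list alone, with Ifitm3 (3.53±0.14, adjusted p = 8.35e-09) (list adjusted p = 0.000226, and 0.0345 with an estimated correlation). Sterol genes rose, 11 up and 0 down of 16, 11 and 0 over the list alone, with Mvd† (2.19±0.13) (list adjusted p = 0.000191, and adjusted p = 0.258 with an estimated correlation). KMT2A fusion targets did not pass as a list (4 up and 16 down of 24, 4 and 17 over the list alone, median -0.54, list adjusted p = 0.059), with Meis1 and Mef2c lower and Prom1 (3.10±0.13) higher. Cell cycle (2 up and 9 down of 25), B cell, MHC class II, stress (4 up and 9 down of 22), p53, stem cell and inhibitor target lists did not pass. Their adjusted p was 0.689, 0.813, 0.813, 0.813, 0.75, 0.689 and 0.993. Markers of other cell types did not pass either (4 up and 1 down of 9, list adjusted p = 0.216), and of these the mast cell gene Hdc† (3.45±0.25) rose. Calls numbered 8643 of 13365 genes (3811 up, 4832 down), around an all-gene median of -0.10.

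The GAPDH 3' minus 5' value was 1.5 and 2.05 on mouse combination replicates 2 and 3, 0.597 on combination replicate 1 and 0.44 to 0.654 on the other mouse arrays. With replicate 1 as the combination array, an alternative added after seeing the data, 8176 genes were called, 6686 of them in the same direction as with 3 arrays.

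Against EPZ004777 the mouse combination called 8481 genes, with higher Erc2 (6.34±0.18) and lower Bcat1 (-5.63±0.59), a branched-chain aminotransferase, and a lower MYC list (0 up and 19 down of 20, list adjusted p = 2.34e-06, and adjusted p = 0.0501 with an estimated correlation). Against MI-2-2 it called 8372 genes, with a lower MYC list (0 up and 19 down of 20, list adjusted p = 8.44e-07, and adjusted p = 0.0501 with an estimated correlation). The single compounds differed for 67 genes, among them Grk3† (2.57±0.25), a receptor kinase, higher with EPZ004777. Without any 1 of their 6 arrays the number was 13 to 37. The sterol list was lower with EPZ004777 than with MI-2-2 (0 up and 3 down of 16, 0 and 11 over the list alone, list adjusted p = 2.15e-17, and adjusted p = 0.0501 with an estimated correlation). A departure from the sum of the single effects was called for 6448 genes, with 2567 up and 3054 down beyond the sum and 827 short of it. Plbd1 (5.84±0.25), a phospholipase, lay above the sum and Bcat1 (-6.41±0.83) below it, as did the MYC list (0 up and 18 down of 20, list adjusted p = 2.77e-07, and 0.0335 with an estimated correlation).

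The correlation across genes of the log2 changes of the single compounds was 0.634 in MOLM-13 (0.617 to 0.657 with 1 array left out) and 0.792 in the mouse cells (0.740 to 0.809), where simulation of the shared DMSO arrays gave 0.50 for both. It was 0.529 in REH (0.448 to 0.674, simulated 0.50), 0.473 in RS4;11 (0.451 to 0.558, 0.600) and 0.419 in SEM (0.337 to 0.476, 0.547). The covariance exceeded its simulated mean by 0.0268, 0.0440, 0.0216, 0.0764 and 0.0978 in RS4;11, SEM, REH, MOLM-13 and the mouse cells. Both single compounds raised 270, 263, 28, 839 and 343 genes in these models, where unrelated calls would give 37.7, 61.4, 1.65, 220 and 18.3. Both lowered 110, 224, 38, 617 and 119 (19.0, 48.6, 1.53, 148 and 3.74). Part of these excesses may come from the shared DMSO arrays. In REH noisy DMSO replicates 1 and 3 (array weights 0.172 and 0.217) leave similarity open.

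Cell models share no arrays with each other, and genes were called in the same direction in a pair of them more often than the product of the call rates gives in 29 of 30 cases. Calls in opposite directions also exceeded it in 13 of the 30. RS4;11 and SEM shared 248 genes with EPZ004777 (36.1 expected), 576 with MI-2-2 (144) and 1371 with the combination (455). RS4;11 and REH shared 111 (16.5), 33 (10.3) and 269 (103), and SEM and REH 110 (19.3), 33 (13.9) and 339 (131). MOLM-13 and the mouse cells, matched by symbol over 9864 genes, shared 165 (76.4), 119 (48.8) and 2748 (1751). RS4;11 and MOLM-13 shared 215 (137) with MI-2-2, and 236 (139) were called in opposite directions, as were 270 (206) for SEM and MOLM-13 with MI-2-2 and 47 (19.0) for SEM and the mouse cells with EPZ004777. For REH and the mouse cells with the combination the number was 206, below the 209 expected. In all 4 models with a rearranged KMT2A, the combination raised 122 genes (8.83 expected), among them ABCA1, MPEG1 and CCNA1, and lowered 160 (19.3), among them MYO6, STC2, BCAT1 and MEF2C. Of these, 19 and 4 were called in the same direction in REH, which has no fusion. EPZ004777 raised 9 genes in all 4 (0.0386 expected), SLC40A1 and TGFB2 among them, and lowered PBX3. MI-2-2 raised 6 (0.117), with FCGR2B, IPCEF1 and CD300LF, and lowered ITGA6, JPH1, FLT3 and SATB1. These names were read after the overlap was seen.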

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

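Of the tests in this part, those of the mouse 3' bias, the REH DMSO spread, and both tests of the MOLM-13 interferon level were chosen only after the result was seen, as were the fits that leave out a pair of arrays, use array weights or a 3' minus 5' covariate, vary the REH ratio or standard errors, or take the mouse slopes from separate arrays. The results that stand out are differences of the effect in RS4;11 and SEM from REH, each by a test of the difference itself. As given above, 784, 2036 and 3099 genes differed. With EPZ004777 the lists that differed were B cell differentiation (0.0339, upward by the test and by the mean of 0.20 while the median was -0.0069), cell cycle (0.00108, downward), interferon response (0.000706, downward) and p53 targets (0.000512, upward), with 0.261, 0.395, 0.099 and 0.067 under an estimated correlation. With MI-2-2 they were myeloid differentiation (7.49e-05, upward), B cell differentiation (0.0246, upward), MYC and ribosome biogenesis (0.0297, downward), MHC class II (0.0223, upward), stress (5.68e-09, downward) and p53 targets (0.0246, upward), with 0.0363, 0.221, 0.426, 0.395, 0.0724 and 0.221 under an estimated correlation. With the combination they were KMT2A fusion targets (0.0406, downward), myeloid (1.31e-05, upward), B cell (0.0231, upward), MYC (0.046, downward), MHC class II (0.00095, upward), stress (1.69e-11, downward), p53 (0.000477, upward) and stem cell genes (0.0342, downward), with 0.0879, 0.0334, 0.221, 0.495, 0.221, 0.0565, 0.067 and 0.0879 under an estimated correlation. These values are adjusted p, and of the 18 list calls the 9 named here held without any single array and in the other settings apart from the estimated correlation: cell cycle, interferon and p53 with EPZ004777, myeloid and stress with MI-2-2, and myeloid, MHC class II, stress and p53 with the combination. The calls ended without REH DMSO replicate 1 (B cell with each treatment, adjusted p up to 0.204, MHC class II with MI-2-2, up to 0.173, MYC with MI-2-2 and the combination, up to 0.207 and 0.244), REH DMSO replicate 2 (p53 with MI-2-2, up to 0.0847, B cell with EPZ004777, and KMT2A targets, MYC and stem cell genes with the combination, up to 0.139, 0.244 and 0.124) or REH DMSO replicate 3 (p53 with MI-2-2, KMT2A targets and stem cell genes with the combination). Other arrays that ended a call were REH EPZ004777 replicate 2 (B cell with EPZ004777), REH MI-2-2 replicate 2 (MYC with MI-2-2), and for KMT2A targets with the combination SEM combination replicate 3, SEM DMSO replicate 3 and REH combination replicate 1. For MYC with the combination they were RS4;11 combination replicate 2, RS4;11 DMSO replicate 3, SEM combination replicate 1, SEM DMSO replicates 2 and 3 and REH combination replicates 1 and 3, each alone. Other settings that ended a call were the replicate block (MYC with the combination), quantile normalization again (KMT2A targets and MYC with the combination), the actin or GAPDH covariate (KMT2A targets with the combination, up to 0.157), the GAPDH covariate (stem cell genes with the combination, 0.126), the mean of probe sets (B cell and MHC class II with MI-2-2, stem cell genes with the combination), array weights (B cell with EPZ004777, MYC with the combination) and leaving out REH DMSO replicates 1 and 3 (B cell with EPZ004777, MYC with MI-2-2 and the combination).

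The first pattern is the mouse combination, for which several times as many genes were called as for either compound, 8643 against 749 and 703. RNA degradation in combination replicates 2 and 3 was argued against as the whole cause: the change of replicate 1, whose GAPDH 3' minus 5' value was that of the other groups, had a slope of 0.745 on that of replicates 2 and 3 over genes called with all 3 and from the same DMSO arrays, and of 0.679 to 0.753 over genes called without replicate 1 and from separate DMSO arrays, and replicate 1 as the combination array gave 8176 called genes against at most 1963 for a single compound. A part played by 3' bias in the gap between replicate 1 and the others cannot be told apart from a difference in response, since their GAPDH values lay 1.18 apart along with it. A joint effect of both compounds stays open: 51.4% of genes (6875) departed from the sum of the single effects with replicate 1 as the combination array, a count that restates the pattern and so tests nothing further.

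The second pattern is the 24 genes called in REH where MI-2-2 was added to EPZ004777, against 2719 in RS4;11 and 3754 in SEM. The spread of the REH DMSO arrays was argued against, since in fits without DMSO arrays the contrast called 110 genes in REH, 2568 in RS4;11 and 3276 in SEM. Lower REH precision was argued against, but not in every setting. Residual SD without DMSO arrays was 0.115 against 0.109 in RS4;11 (REH 0.152 with them), where REH standard errors would leave 2087 of 2295 calls. The SD of changes net of standard errors was 0.432 times that of RS4;11 (0.372 to 0.515 without 1 array, 0.513 with array weights). Under 0.5 was preset to exclude it and at least 0.75 to bear it out. The size of the gap depends on the weight of the arrays. REH is the lone line without a KMT2A fusion, so a role of the fusion was not tested.

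The third pattern is the lower level of interferon response genes in all 3 treated MOLM-13 groups than in DMSO. A single unusual DMSO array was argued against: with each DMSO array left out in turn, at least 15 of the 20 members were called lower in each treatment. A state of the DMSO cultures unrelated to the compounds cannot be told apart from an effect that both compounds have, because the lowest DMSO array lay 1.21 log2 above the highest treated array and the gap follows the groups of the design. The DMSO arrays themselves had mean levels of 8.97, 9.82 and 9.39. The treated groups did not share one level, as a DMSO state alone would have it: 7.57 to 7.75 with EPZ004777, 7.24 to 7.40 with the combination and 7.04 to 7.12 with MI-2-2. For EPZ004777 minus MI-2-2 the list had 10 up and 0 down of 20 (list adjusted p = 3.90e-05, and adjusted p = 0.393 with an estimated correlation), which leaves the gap they share open.

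Other splits of the same arrays were too few for a share under 0.05 in each comparison of 3 with 3 arrays (10 splits), where 1 split, the real one, called as many genes. For EPZ004777, MI-2-2 and the combination against DMSO, then the combination against EPZ004777 and against MI-2-2 and EPZ004777 against MI-2-2, real counts and the highest of the other splits were 3941 and 1, 2629 and 0, 6947 and 0, 4690 and 0, 5576 and 0, and 2958 and 0 in MOLM-13. In REH they were 574 and 1, 187 and 0, 1045 and 1, 24 and 0, 280 and 0, and 389 and 0, and in the mouse cells 749 and 0, 703 and 0, 8643 and 0, 8481 and 0, 8372 and 0, and 67 and 0. In RS4;11 the last 3 comparisons gave 2719 and 0, 1501 and 1, and 2255 and 1. For the interaction, 1 of 100 regroupings, the real one, called as many genes in MOLM-13 (1816, highest other 672) and in the mouse cells (6448, highest other 6236), and 100 of 100 in REH (real 0 with limma and 739 at an unadjusted p under 0.05, highest other 626). These counts decide nothing about chance, since regrouped arrays mix groups with treatment effects and a real count of 0 is always reached.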

How the results depend on the processing

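Of the alternatives, those without REH DMSO replicates 1 and 3, without mouse combination replicates 2 and 3, with a 3' minus 5' covariate and with array weights were chosen after seeing the data, and the cause of a change was not tested except where fewer arrays make a test less precise. Of 480 list tests, 470 gave the same outcome after quantile normalization again, 464 with no filter and 474 with replicate number as a block, 441 of 470 with the mean of probe sets, 365 of 389 in the fit shared by the human arrays, and 309 with an estimated correlation, which ended 171 calls. Leaving out each array kept 3264 of 3426 list outcomes, ended 115 calls and added 47, and kept 3670 of 4164 gene outcomes, ending 492 calls and adding 2. The named genes kept their outcome in 678 of 704 cases with no filter, 695 with quantile normalization, 630 of 671 with the mean of probe sets, 633 of 704 with the block, 523 of 562 in the shared fit, 58 of 163 with the actin covariate and 90 of 120 without REH DMSO replicates 1 and 3. Replicate numbers share only a number, as far as the labels say: pairs of arrays with the same number correlated above 0.1 after removal of group means in 2 of 15, 2 of 10, 5 of 18, 3 of 18 and 9 of 18 cases in RS4;11, SEM, REH, MOLM-13 and the mouse cells. With no filter and quantile normalization the correlations between compounds moved by less than 1 SD of their values with an array left out, which reach on both sides of the simulated value in REH, and signal over background on the arrays limits what can be said of dim genes, which the filter left out.

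The outcomes that reversed were, with the actin covariate in SEM, the stress list for EPZ004777 minus MI-2-2 (adjusted p = 0.986, between 2.55e-10 and 0.986 over its alternatives), MECOM and TRAT1 with the combination (-1.08 and -0.63) and CENPA and STC2 with MI-2-2 (-0.0029 and 0.27), and in the shared fit ITGB8 in SEM with EPZ004777 (0.0535), HLA-DQA1 in REH with the combination and EPZ004777 (-0.41 and -0.53), PAX7 in REH for combination minus EPZ004777 (-0.0503) and MYCN in REH with EPZ004777 (-0.0787). Each group keeps its own mean in the shared fit, so a change of sign there means that another probe set of the gene was taken.

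Counts moved over 1.5 times in these cases, in the order EPZ004777, MI-2-2, combination, combination minus EPZ004777, combination minus MI-2-2, EPZ004777 minus MI-2-2 and interaction. With the block, SEM gave 614, 1390, 2697, 424 (combination minus MI-2-2), 2017 and 61, RS4;11 159 (interaction), and REH 41 (MI-2-2) and 6 (combination minus EPZ004777). In the shared fit REH gave 1541, 1998, 2913, 136, 503, 1061 and 11, and the SEM interaction 287. With the actin covariate, which is nearly collinear with treatment, SEM gave 338, 0, 14, 0 (combination minus EPZ004777), 0 (EPZ004777 minus MI-2-2) and 49 (interaction) in limma, with 924, 1294 and 1286 genes at an unadjusted p under 0.05 beside the 3 counts of 0. With the GAPDH covariate REH gave 1045 (EPZ004777), 42 (combination minus EPZ004777), 746 (EPZ004777 minus MI-2-2) and 1 (interaction), the mouse cells 1435, 1434 and 310 (EPZ004777 minus MI-2-2), and the line difference 1622 with EPZ004777. Array weights in REH gave 865, 119, 1648 (combination minus EPZ004777), 812, 3109 and 6, with a weight of 7.02 on EPZ004777 replicate 1. Without REH DMSO replicates 1 and 3, REH gave 29 (MI-2-2), 511, 110, 538 and 1105, and the line difference 1117 with MI-2-2. Without mouse combination replicates 2 and 3 the mouse cells gave 1963, 1859 and 516 (EPZ004777 minus MI-2-2). REH combination minus EPZ004777 gave 10 with quantile normalization and 11 with the mean of probe sets. At an adjusted p under 0.01 the overlaps with EPZ004777, MI-2-2 and the combination were 92, 230 and 693 for RS4;11 and SEM, 49, 6 and 106 for RS4;11 and REH, 35, 1 and 126 for SEM and REH, and, for MOLM-13 and the mouse cells, 72 with EPZ004777 and 48 with MI-2-2.

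With 1 array left out, the lowest and highest counts in the same order were 353 and 770, 760 and 1502, 1810 and 3320, 981 and 1325 (combination minus MI-2-2), 1482 and 1823, and 107 and 264 in RS4;11. In SEM they were 296 and 1755, 1143 and 1528, 2500 and 2804, 2041 and 3828, 249 and 354, 1350 and 3585, and 49 and 167. In REH they were 308 and 1058, 19 and 1314, 473 and 2028, 0 and 1, 150 and 189, and 218 and 317, the 0 from limma beside 617 to 1001 genes at an unadjusted p under 0.05. The MOLM-13 interaction gave 1186 and 2196, the mouse cells 456 and 628, 416 and 671, and 13 and 37 (EPZ004777 minus MI-2-2), and the line difference 530 and 1884 with EPZ004777 and 1410 and 3177 with MI-2-2. A lone array left in a group was taken to vary like those of the other groups.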

Other observations

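The liver X receptor test was planned before its further genes were looked at, but its pattern and its gene list were chosen after ABCA1 and ABCG1 had been seen. The cholesterol exporter gene ABCA1† changed by 2.01, 4.44 and 4.74 log2 in MOLM-13 with EPZ004777, MI-2-2 and the combination, by 1.64, 2.73 and 3.06 in RS4;11, and by -0.04 (not called), 2.84 and 2.80 in SEM. ABCG1† changed by 2.52, 8.09 and 8.82 in MOLM-13, by 1.48, 3.48 and 4.18 in RS4;11 and by 0.74, 0.74 and 1.31 in REH. ABCA1† was not called in REH nor ABCG1† in SEM. In the mouse cells Abca1 changed by 0.26 and 1.00 (not called) and 3.85, and Abcg1 was not called. MI-2-2 in MOLM-13 also raised SREBF1 (1.11), SMPDL3A (1.96), LPCAT3 (0.59) and MYLIP (0.41), liver X receptor targets outside the test.

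As both exporters are targets of the liver X receptors, a candidate explanation is activity of liver X receptors in MI-2-2 treated MOLM-13 cells. Of 5 further target genes measured there, 2 were called higher with MI-2-2, PLTP (1.12) and EEPD1 (0.66), and 1 lower, CETP (-0.31), a number between those that would have borne the explanation out and argued against it, so it stays open. The sterol synthesis genes fell in the same cells with MI-2-2 (7 of 15, adjusted p = 0.354 with an estimated correlation) and rose in the mouse cells (12 of 16), and no test here links the observations.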
